A study of Mus musculus with 12 samples.

How the data were processed

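RNA-seq of white fat was analysed in 12 libraries, from the epididymal pad (epWAT) and the subcutaneous pad (scWAT) of 6 mice. Of these mice 3 were wild type (WT) and 3 lacked C2orf74 (KO). Per the labels, high-fat feeding began at 8 weeks of age and lasted 12 weeks. RNA was extracted with Trizol and libraries followed the manufacturer's usual Illumina procedure, per the labels' protocols. The aligner, the counting program, the annotation and the strand setting were not given in the sources used here, and mm9 was the build named in the submitters' processing notes.

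The deposited values were in FPKM, 1 value per Ensembl gene and library, with 32622 genes in each file. The unit was inferred from the values, and whether the authors counted reads or fragments was not stated. Multiplying a value by the gene's exon length in GENCODE release M21 (GRCm38) and by 1 depth per library gave whole numbers, within 0.01, in all 12 libraries for 92.4% of genes. These depths were 15011093 to 18311564 reads. Gene lengths thus followed a GRCm38-type annotation although the notes named mm9, so coordinates are given only for GRCm38 from GENCODE M21. Of the identifiers, 32553 matched that annotation and 69 did not. Intervals and floors cover counting error only, and a floor of 3 reads was used.

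The following choices were made before the data were examined: groups, tests, filters, 42 gene lists, alternatives and the rule for named genes. Genes with FPKM of at least 1 in at least 3 libraries of a fit were tested with limma-trend on log2(FPKM + 1), with Benjamini-Hochberg adjusted p under 0.05 as the threshold. Fold changes are on that scale, which understates changes of low genes. KO was compared with WT in each depot on its own 6 libraries. The interaction, meaning the KO effect in scWAT minus that in epWAT, used all 12 libraries, and the depots were compared within each genotype. Because the values were normalized, the count tests planned for the case of raw counts were not used. Gene lists with at least 3 tested members were tested with camera at a preset correlation of 0.01, again with an estimated correlation, and with fry. Camera compares the members of a list with all other tested genes, so its directions are relative to those genes. Named genes were the targeted gene, the 10 higher and 10 lower genes with the smallest p among non-overlapping calls per depot (the 5 smallest p as values where fewer than 5 passed in a direction), 21 adipose genes fixed by name, up to 4 members of each list called or with 3 or more called members, the 10 smallest p of the interaction and up to 6 members of each depot list. Genes with symbols of the forms Gm, LOC, BC, AK or AI with a number, or ending in Rik, were left out of the ranking for KO against WT in each depot, but not for the interaction.

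Mouse codes in the titles occur in both depots and were read as animals. Deviations from group means correlated between the depots of the same mouse at -0.03 for C7, 0.17 for C34, 0.11 for C695, 0.36 for C75, 0.32 for C85 and 0.26 for C99, against at most 0.06 with any other mouse of the same genotype; C7 and its own other depot thus did not pair by this measure. Because the pairs come from the same animals, fits with the mouse as a block were run for the interaction and the depot comparisons. Mice are nested in genotype, so for KO against WT in a depot the mouse could enter only as a random effect over all 12 libraries.

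Alternatives were no filter, a stricter filter (FPKM of at least 5), pseudocounts of 0.1 and 5, upper-quartile and quantile scaling, a spread shared over 12 libraries, the mouse as a random effect, robust moderation, a minimum absolute log2 change of 1 and leaving out each library. After seeing the data, limma-voom on the recovered reads and fits without KO epWAT C7 and KO scWAT C695, which held transcripts of other tissue, were added, as were upper-quartile scaling of the lists and the estimated correlation under each scaling and left-out library. Smaller amounts of such transcripts in other libraries were left in those fits. The procedure was tested on simulated data. In the epWAT simulation of 12813 genes, 55.0% of genes changed 2-fold and 85.6% changed 4-fold were recovered, and 9 unchanged genes were called. In the scWAT simulation of 12869 genes the shares were 64.0% and 92.0%, with 5 unchanged genes called. Simulated noise was drawn independently for each gene and library, without correlation between genes and without libraries holding other tissue. These shares are therefore not the power of the real comparisons. R 4.3.3, limma 3.58.1, statmod 1.5.0, Python 3.11.15, pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9 were used.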

Results

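Gene expression was measured in the epididymal and subcutaneous white fat of WT and KO mice kept on a high-fat diet. Each of the 4 groups held 3 libraries, and each of the 6 mice gave 1 library per depot. Recovered depths were 15011093 to 17294388 reads in KO epWAT, 17574947 to 18263864 in WT epWAT, 16828570 to 17470262 in KO scWAT and 16192574 to 18311564 in WT scWAT. Transcripts of other tissues were present in several libraries. The KO epWAT library of mouse C7 had 219.1 FPKM of the epididymal secretory gene Crisp1 and 49.2 FPKM of the sperm protamine gene Prm1. Of 22 detected epididymis and germ cell markers, 19 were highest in it. Crisp1 was at 6.3 FPKM in KO epWAT C695 and at most 0.218 FPKM in the other libraries. The KO scWAT library of mouse C695 had 75.8 FPKM of the B cell gene Cd79a, and 29 of 32 detected B cell, T cell and NK cell markers were highest in it. The muscle creatine kinase gene Ckm was at 13.8 FPKM in KO scWAT C34, 5.5 FPKM in KO scWAT C695 and 4.13 FPKM in WT scWAT C75.

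**Figure D1:**
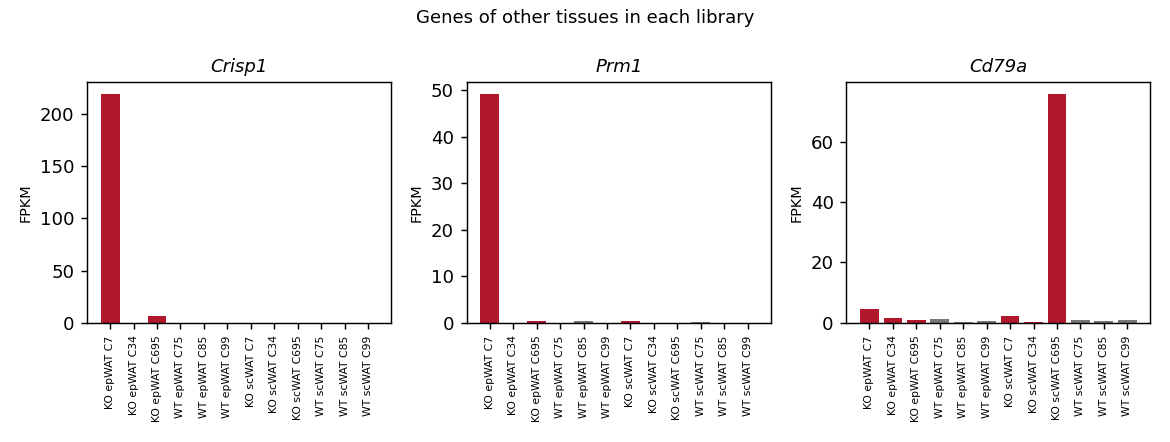
FPKM of Crisp1, Prm1 and Cd79a (vertical axes, linear) in each of the 12 libraries, with KO in red and WT in grey. Crisp1 reached 219.1 FPKM in KO epWAT C7 and Cd79a reached 75.8 FPKM in KO scWAT C695.

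The targeted gene was examined first as a check of the genotype labels. Human C2orf74 was taken to correspond to mouse 1700093K21Rik (ENSMUSG00000020286), a protein-coding gene on the minus strand of chromosome 11, positions 23516203 to 23521155 in GRCm38. It was close to undetected in every library. In epWAT it had 1 read over the 3 KO libraries and 7 over the 3 WT libraries, a KO to WT ratio of 0.157 per read sequenced (95% exact interval 0.00347 to 1.22). In scWAT the sums were 2 and 20 reads, a ratio of 0.102 (0.0115 to 0.419). All KO reads in both depots came from mouse C7, whose 2 reads in scWAT compare with 3 in WT scWAT C99. This gene thus does not separate those 2 libraries. Mean values in scWAT were 0.0197 ± 0.0341 FPKM in KO and 0.19 ± 0.0964 FPKM in WT (SD, n = 3; two-sided exact permutation p = 0.1, the smallest that 3 against 3 allows). In epWAT the permutation p was 0.4 at 3 libraries per group, and the WT library C75 had 0 reads, so the labels could not be checked there at this depth.

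KO epWAT had lower values of macrophage genes and higher values of mature adipocyte and mitochondrial genes than WT epWAT, but no single gene passed the test. Of 29 measured macrophage markers, 28 were lower, with a median log2 change of -1.30, and the exception was Lpl, a lipase that adipocytes also express. Adgre1, which encodes the macrophage antigen F4/80, averaged 30.5 ± 18.6 FPKM in KO and 95.3 ± 22.1 in WT (SD, n = 3; limma Benjamini-Hochberg adjusted p = 0.0739). The chemokine receptor gene Ccr2 averaged 4.89 ± 0.288 against 18.6 ± 4.31 FPKM, a log2 difference of -1.71 ± 0.17 (SE; adjusted p = 0.0533). Among adipocyte genes, Cfd, which encodes adipsin, averaged 3266.6 ± 797.4 against 955.8 ± 244.3 FPKM (log2 difference 1.78 ± 0.26 SE; adjusted p = 0.0586).

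The macrophage list was called lower in KO epWAT by camera (adjusted p = 7.82e-06; adjusted p = 0.494 with an estimated correlation). Adjusted over the list alone, 19 members were lower and 1, Lpl, was higher. All 25 cell cycle genes had lower values (median -0.77; adjusted p = 3.27e-05, and adjusted p = 0.564 with an estimated correlation), among them Pcna at 24.2 ± 5.1 against 44.1 ± 9.37 FPKM (SD, n = 3); the list median was -0.50 without KO C695. Sterol synthesis genes had a median of -0.32 (-0.19 after upper-quartile and -0.21 after quantile scaling), and 13 of 23 were lower adjusted over the list alone. That list was called by camera (adjusted p = 0.00198; adjusted p = 0.262 with an estimated correlation) and was the only list called by fry (adjusted p = 0.00194). Its members included Dhcr7, which acts late in the pathway, at -0.70. Unfolded protein response genes had a median of -0.25 (adjusted p = 0.019; adjusted p = 0.564 with an estimated correlation), or -0.10 after upper-quartile scaling (adjusted p = 0.0499; adjusted p = 0.744 with an estimated correlation) and -0.14 after quantile scaling, with Asns higher by 0.88 and Sdf2l1 lower at -1.10.

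Lists with higher values in KO epWAT included the respiratory chain, with 55 of 56 nuclear-encoded members higher and a median of 0.23, or 0.38 after upper-quartile scaling and 0.15 without KO C695 (camera adjusted p = 1.56e-18; adjusted p = 0.41 with an estimated correlation). All 14 mitochondrially encoded genes had higher values (median 0.73; 11 adjusted over the list alone; adjusted p = 2.54e-12, and adjusted p = 0.399 with an estimated correlation). Mitochondrial transcripts made up 10.8% to 13.9% of summed FPKM in KO epWAT and 7.0% to 8.1% in WT epWAT. Mature adipocyte genes had a median of 0.41, with 17 of 35 higher adjusted over the list alone, and tricarboxylic acid cycle genes a median of 0.33, with 16 of 23 (adjusted p = 1.32e-15 and 5.41e-13; adjusted p = 0.399 with an estimated correlation for both). The resistin gene Retn averaged 681.8 ± 170.4 against 269.0 ± 55.3 FPKM and the gluconeogenic and glyceroneogenic enzyme gene Pck1 352.5 ± 123.7 against 116.6 ± 18.4 FPKM (SD, n = 3; adjusted p = 0.066 for both). In all, 22 of 39 lists were called in epWAT, 17 up and 5 down, and 0 with an estimated correlation (smallest adjusted p = 0.262). Lists called up by camera included red cell, B cell, mesothelial and endothelial markers, with medians of 0.44, 0.72, 0.13 and 0.09. Their adjusted p was 0.0437, 0.0209, 0.04 and 0.0364, and 0.564, 0.494, 0.642 and 0.642 with an estimated correlation. None of them was called after upper-quartile or quantile scaling. Immediate early and heat shock genes, which respond to handling of tissue, were among those called up (median 0.26; adjusted p = 0.0431, and adjusted p = 0.642 with an estimated correlation). Their mean log2 value was 5.17 in KO C7, 4.51 in KO C34 and 3.42 in KO C695, against 3.91 to 4.19 in WT, and the median was -0.04 without KO C7 and 0.63 without KO C695. This call was lost after upper-quartile and quantile scaling (adjusted p = 0.334 and 0.316) and without KO C7, KO C34, WT C75 or WT C85. Fatty acid oxidation, lipogenic and insulin or glucose genes were also called up, with medians of 0.20, 0.27 and 0.37, or 0.36, 0.43 and 0.51 after upper-quartile scaling (adjusted p = 1.64e-07, 2.42e-06 and 5.39e-06; adjusted p = 0.399, 0.399 and 0.262 with an estimated correlation). The insulin or glucose list had 0.22 without KO C695. Thermogenic genes were not called (camera adjusted p = 0.221, median -0.08, and 0.06 after upper-quartile scaling). Ucp1 averaged 0.0364 FPKM in KO and 0.0345 FPKM in WT. It was at most 0.103 FPKM in any epWAT library, below the filter, so it was not tested and its means say little.

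**Figure D2:**
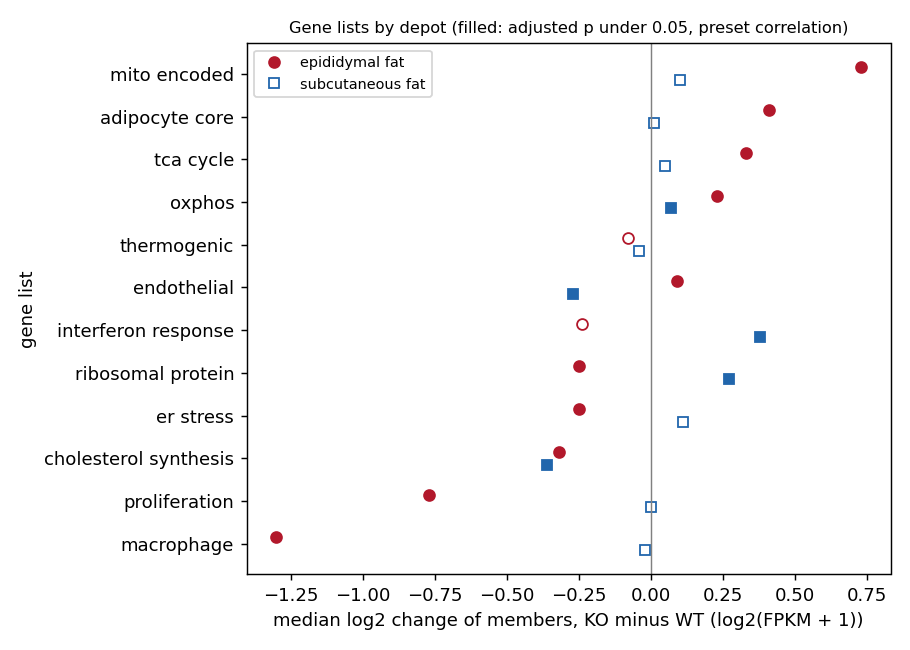
Median log2 change (KO minus WT, log2(FPKM + 1), horizontal axis) of the members of 12 of the fixed gene lists in epididymal fat (red circles) and subcutaneous fat (blue squares). Filled symbols had a camera adjusted p under 0.05 at the preset correlation; none had one with an estimated correlation. The macrophage median was -1.30 in epWAT and -0.02 in scWAT.

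Of 12722 genes tested in epWAT, 0 passed with limma (smallest adjusted p = 0.0533), 3795 had an unadjusted p under 0.05 (911 higher and 2884 lower, against 636 by chance), and limma-voom also called 0, with 3842 at unadjusted p under 0.05. At limma adjusted p under 0.1, scWAT had 260 genes and epWAT 2174 (520 higher and 1654 lower). The 3 KO values lay all above or all below the 3 WT values for 38.8% of genes, against 10% by chance. The smallest p among genes with lower values belonged to Tph2, a tryptophan hydroxylase gene, at 2.13 ± 1.29 against 34.7 ± 5.89 FPKM. Among genes with higher values it belonged to Rprml, at 11.6 ± 1.37 against 3.21 ± 0.367 FPKM (SD, n = 3). The median gene differed by -0.10, and by 0.03 after upper-quartile and after quantile scaling. Upper-quartile scaling called 71 genes higher and 20 lower, and quantile scaling 44 and 46. The cause of these calls was not tested. Without KO C7, the library with epididymal transcripts, 1781 genes passed (334 higher and 1447 lower), and a spread shared over 12 libraries called 1765.

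KO scWAT had lower values of the leptin gene Lep and of the oxytocin receptor gene Oxtr than WT scWAT, and both passed the test. Lep fell from 1676.9 ± 87.6 FPKM in WT to 656.1 ± 111.9 in KO (SD, n = 3; log2 change -1.37 ± 0.14 SE; limma Benjamini-Hochberg adjusted p = 0.0439). Oxtr fell from 40.3 ± 9.26 to 6.17 ± 0.611 FPKM (log2 change -2.50 ± 0.16; adjusted p = 0.0256). The lipopolysaccharide-binding protein gene Lbp fell by 1.02 and the gastric lipase gene Lipf by 2.15 on the log2 scale (adjusted p = 0.0256 for both). Cyp2f2, a cytochrome P450 gene, rose from 1.82 ± 0.556 to 15.0 ± 4.11 FPKM (log2 change 2.49 ± 0.23; adjusted p = 0.0358).

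Of 12614 genes tested in scWAT, 40 passed, 6 higher and 34 lower, and limma-voom called 38. The KO and WT values did not overlap for 24.5% of genes, against 10% by chance. The other 5 that rose were Ly6e (1.02), Tst (1.23), Rprml (1.22), Angpt1 (0.96) and Peli1 (0.76). Trp53inp2, Jpt2, Vgll3, Kcnj14, Duoxa1, AA914427 and Copg2 also fell, by 0.76 to 1.29. Copg2 overlaps the opposite-strand gene Mest by 912 bp in GRCm38 (chromosome 6, Mest 30723547 to 30748465), and the strand setting was not given, so their reads cannot be told apart in the overlap. Mest, named here after its values were seen, fell by 2.18 (adjusted p = 0.0444). Thermogenic genes were not called (median -0.04; adjusted p = 0.667), Adipoq averaged 1816.1 ± 155.0 against 2008.9 ± 76.9 FPKM (adjusted p = 0.536), and Adgre1 averaged 23.8 ± 14.9 against 22.1 ± 4.67 FPKM (SD, n = 3; limma adjusted p = 0.916). The macrophage list had a median of -0.02 in scWAT, or 0.41 without KO C695 (adjusted p = 0.000223; adjusted p = 0.689 with an estimated correlation) and -0.25 without KO C34 (adjusted p = 0.025; adjusted p = 0.806 with an estimated correlation). Leaving out 1 library gave 0 calls for KO C7, WT C85 and WT C99, 1 for KO C34 and WT C75, and 142 for KO C695, the library with B cell transcripts.

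Of 38 lists in scWAT, 7 were called, 5 up and 2 down, and 0 with an estimated correlation. Those called up included 3 also called up in epWAT: the respiratory chain, glucocorticoid-responsive and insulin or glucose genes. Their medians were 0.07, 0.31 and 0.21 (camera adjusted p = 0.017, 0.0286 and 0.0286, and 0.994, 0.989 and 0.819 with an estimated correlation). The depots share mice, and WT C75 had the lowest mean log2 value of the glucocorticoid list in both (4.42 in epWAT, 4.55 in scWAT). The other WT libraries overlapped KO. In epWAT they had 4.95 to 4.96, against 4.92 to 5.28 in KO. In scWAT they had 4.99 to 5.13, against 5.08 to 5.59 in KO. Sterol synthesis genes had a median of -0.36 and 9 of 23 members lower adjusted over the list alone (camera adjusted p = 8.23e-08; adjusted p = 0.819 with an estimated correlation). Immediate early and heat shock genes were not called in scWAT (median 0.36; adjusted p = 0.186) but were without KO C695 (0.75; adjusted p = 0.000541, and adjusted p = 0.727 with an estimated correlation), with a median of -0.06 without KO C34, whose mean log2 value was 4.80 against 3.31 to 4.08 in the other libraries. Endothelial markers had a median of -0.27, or -0.15 without KO C34, with 5 of 20 lower adjusted over the list alone (adjusted p = 0.000405; adjusted p = 0.819 with an estimated correlation). Among them, Cdh5, the VE-cadherin gene, averaged 46.1 ± 5.24 against 61.6 ± 0.745 FPKM (SD, n = 3; limma adjusted p = 0.118). Pericyte and smooth muscle markers had a median of -0.31, with 10 of 13 lower; adjusted over the list alone, 6 were lower and 2 higher. Red cell markers had -0.73, with 5 of 5 lower; neither list was called (adjusted p = 0.124 for both). The pericyte list was called without KO C34 or KO C695 (adjusted p = 0.0117 and 0.0152; adjusted p = 0.8 and 0.689 with an estimated correlation), and the red cell list without WT C99 (median -1.26; adjusted p = 1.87e-07, and adjusted p = 0.76 with an estimated correlation). Interferon-stimulated genes had a median of 0.38, or 0.24 without KO C34, with 25 of 30 higher (adjusted p = 0.000256; adjusted p = 0.819 with an estimated correlation). All 39 ribosomal protein genes were higher in scWAT (median 0.27, and 0.16 without KO C695, the library with lymphocyte transcripts; adjusted p = 1.76e-11, and adjusted p = 0.941 with an estimated correlation) and all 39 lower in epWAT (median -0.25, and -0.09 after upper-quartile scaling; adjusted p = 0.000177, and adjusted p = 0.642 with an estimated correlation).

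**Figure D3:**
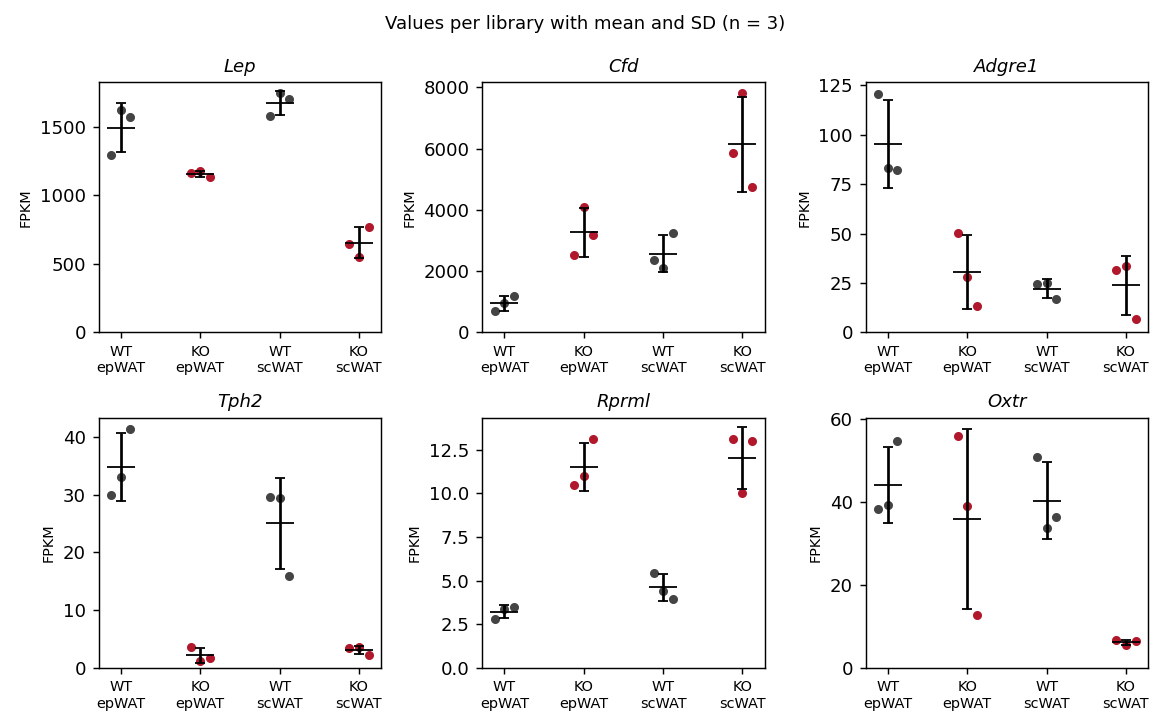
FPKM (linear vertical axes) of Lep, Cfd, Adgre1, Tph2, Rprml and Oxtr in each library, KO in red and WT in grey, with mean and SD of 3 libraries. Lep averaged 656.1 FPKM in KO scWAT and 1676.9 FPKM in WT scWAT.

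The interaction asked whether the KO difference depended on the depot. Without blocking by mouse, 139 of 13487 genes passed, 79 with the higher KO minus WT log2 difference in scWAT and 60 with the lower (37 and 156 with upper-quartile scaling, 77 and 125 with quantile scaling). Lep had a log2 difference between depots of -1 (limma adjusted p = 0.042), its KO effect being -1.37 in scWAT and -0.36 in epWAT. The lipoprotein lipase gene Lpl had -0.98 (adjusted p = 0.0383), with effects of -0.34 in scWAT and 0.64 in epWAT. Nexn, an actin-binding protein gene, had -1.37 and Mcam, a cell adhesion gene, -0.87 (adjusted p = 0.0196 for both). With the mouse as a block, 0 genes passed by limma (smallest adjusted p = 0.0619; 3483 at unadjusted p under 0.05), while limma-voom without the block called 128. Without KO epWAT C7 and KO scWAT C695, 1477 genes passed without the block. Leaving out 1 library gave 928 genes for KO epWAT C7, 42 for KO epWAT C695, 27 for KO scWAT C34, 16 for WT epWAT C99, 8 and 2 for WT scWAT C85 and C75, 1 for WT epWAT C75, and 0 for KO epWAT C34, WT epWAT C85 and WT scWAT C99.

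The depot comparison checked the depot labels. Among genes known from subcutaneous fat, the following developmental regulator genes were higher in scWAT of WT mice: Tbx15 (4.73 ± 0.553 against 0.01 ± 0.0174 FPKM), Hoxc10 (8.72 ± 2.19 against 0.0592 ± 0.052) and Hoxc9 (8.35 ± 0.782 against 1.78 ± 0.284). Among those of the epididymal pad, log2 changes in scWAT were -1.62 for Tcf21, -3.87 for the mesothelial gene Upk3b and -2.24 for the angiotensinogen gene Agt (limma adjusted p = 0.00253, 0.00528 and 0.0092). Nnat and Hoxc8, also listed as epididymal, were higher in scWAT, at 1.62 and 0.32 (adjusted p = 0.00879 and 0.0196), and some members of both lists did not pass; Hoxc8 is named in this comparison after its values were seen. In WT, 2852 of 12760 genes passed, 956 higher in scWAT and 1896 lower (1341 and 1484 with upper-quartile scaling). In KO, Tbx15, Hoxc10, Upk3b and Msln also differed, at 2.79, 2.53, -3.95 and -3.47, and 90 of 12623 genes passed, 36 higher and 54 lower, or 12 with the mouse as a block. The difference between these counts was not itself tested. The KO and WT epididymal pads were also compared in these markers. Camera called the epididymal list (median 0.17; adjusted p = 0.000376) and the subcutaneous list (median 0.14; adjusted p = 0.0209) up in KO epWAT. With an estimated correlation the adjusted p was 0.494 and 0.399, and the subcutaneous call was lost after upper-quartile scaling (adjusted p = 0.0636). Mean log2 values of the epididymal list overlapped, at 4.05 to 4.34 in KO epWAT and 3.19 (C75), 3.83 (C99) and 4.31 (C85) in WT epWAT. Those of the subcutaneous list did not, at 2.07 to 2.10 in KO epWAT and 1.80 to 1.91 in WT epWAT. Hoxc9 was at 3.33 to 4.28 FPKM in KO epWAT and 1.55 to 2.1 in WT epWAT. The cause was not tested.

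Across the 12183 genes tested in both depots, the KO effects had a Pearson r of 0.14 and a Spearman rho of 0.04; genes are not independent replicates. The same mice gave both depots, so a relation can arise without any effect of genotype, and other splits of the 6 mice into 3 and 3 gave r from 0.04 to 0.31. The KO effects were therefore no more alike between depots, by this measure, than effects of regrouped mice. Their covariance was 0.0165, against at most 0.0146 in the other splits. Regrouped mice still carry part of any genotype effect, so those splits are not free of it. In both depots Tph2 was lower (-3.57 and -2.63) and Rprml higher (1.57 and 1.22), with Tph2 and Rprml past the threshold in scWAT. Genes with an unadjusted p under 0.05 and the same direction in both depots numbered 434, namely 125 higher and 309 lower, where independent lists of those sizes would share 58.8 and 282.5. Lists from depots of the same mice are not independent, and regrouped mice also shared more genes than independent lists would. Genes going opposite ways numbered 219, against 272.2 for independent lists.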

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

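The tests of other tissue, of the macrophage markers and of every split of the libraries named here except those of the gene lists were chosen after the results were seen. The KO effect differed between depots for 139 genes by the interaction test without blocking by mouse, and for 0 with it. Among the named genes these differences of log2 effect (scWAT minus epWAT) were -1.37 for Nexn, 0.82 for Samd1, 1.33 for Gngt2, -1.40 for Efcab8, -1.27 for Lmo1, 0.62 for Orai3, -0.87 for Mcam, 2.15 for Gm15433, 0.88 for Josd2, -0.72 for Gpc4, -1.11 for Hoxc9, -0.71 for Mpc2, 1.27 for Htr2b, -0.98 for Lpl, -1 for Lep, -0.72 for Asns, -0.83 for Trp53inp2, -0.48 for Jpt2 and -0.83 for Enpp2. The 10 splits of the 6 mice cannot give a share under 0.05. The real split gave 139 genes and was the only 1 of the 10 splits to give as many, the highest other split giving 0.

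Macrophage markers had lower values in KO epWAT. A smaller share of all non-adipocyte cells would lower the endothelial, mural, progenitor and mesothelial markers alike, but the macrophage list minus the mean of those 4 lists differed by -1.50 on the log2 scale between KO and WT (SE 0.51), with 0.68 to 1.99 in KO libraries and 2.20 to 3.38 in WT libraries. Scaling is argued against as the whole source, since the list median was -1.14 after upper-quartile scaling, and so is RNA of the epididymis in KO C7, since the median was -1.58 without it (-1.02 without KO C695, which had less of it). Fewer macrophages in KO epWAT may therefore be a candidate explanation, as may lower expression per macrophage, and bulk RNA does not separate them. The inflammation list was not called in epWAT, with 10 members higher and 15 lower (camera adjusted p = 0.971). Its mean log2 value was 4.19 in KO C7, 2.93 in KO C34 and 2.26 in KO C695, against 3.16 to 3.43 in WT. The macrophage list call itself was lost with an estimated correlation, and 2 of the 10 splits of mice gave at least the 22 called lists of the real split, the highest other giving 24.

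Transcripts of other tissue stood out in several libraries. Of 22 detected epididymis and germ cell markers, 19 peaked in KO epWAT C7, Crisp1 reaching 219.1 FPKM. That library may hold a piece of epididymis, with or without testis. The epididymal gene Gpx5 was at 0 FPKM in all 12 libraries, KO epWAT C7 included. KO epWAT C695 had Crisp1 at 6.3 FPKM and Adam7 at 0.446 FPKM, so 2 of the 3 KO epWAT libraries showed epididymal genes, and C695 stayed in the fits without C7. Of 32 detected B, T and NK cell markers, 29 peaked in KO scWAT C695, which may hold lymph node tissue, Cd79a reaching 75.8 FPKM. No biological explanation was tested, and an effect of genotype on the amount of such tissue stays open beside dissection.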

How the results depend on the processing

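The fits with voom, those without KO epWAT C7 and KO scWAT C695, the lists after upper-quartile scaling and the estimated correlation under each scaling and left-out library were chosen after seeing the data, and tests for raw counts were not run because the files hold FPKM. In epWAT, 0 genes passed; the stricter filter gave 39, a pseudocount of 5 gave 29, upper-quartile scaling 91 (71 higher and 20 lower), quantile scaling 90 (44 and 46), a spread shared over 12 libraries 1765 and the mouse as replicate block (random effect) 1759. No filter, a pseudocount of 0.1, robust moderation and voom left 0. Leaving out 1 library gave 0 to 1781, the top without KO C7. In scWAT, the 40 calls became 11 with no filter, 72 with the stricter filter, 23 with a pseudocount of 5, 23 with upper-quartile scaling, 22 with quantile scaling, 21 with robust moderation, 24 with a log2 change of at least 1, 251 with the shared spread and 265 with the replicate block. Leaving out 1 library gave 0 to 142, the top without KO C695; the cause was not tested. The 139 interaction genes became 23 with no filter, 0 with the mouse as replicate block, 1477 without KO epWAT C7 and KO scWAT C695 and 1687 without them and with the block, a count in which only mouse C34 gives a KO pair of depots, so that the KO side has no replicate and it is no test against the 0; scaling by upper quartile turned the split to 37 and 156 and by quantile to 77 and 125. Leaving out 1 library gave 0 to 928, the top without KO epWAT C7; the cause was not tested. For the depots in WT, where scaling by upper quartile gave 1341 higher and 1484 lower and by quantile 1413 and 1502, the range without 1 library was 1272 to 2307 (1777 and 1760 without WT epWAT C75 and C99, 1563 and 1272 without WT scWAT C85 and C99) and the block gave 3806. In KO, the 90 calls became 44 with no filter, 55 with the stricter filter, 12 with the block and 6 without KO epWAT C7 and KO scWAT C695, and 7 to 36 without 1 library. The 22 called lists in epWAT became 0 with an estimated correlation and 1 with fry, and 17 to 24 without 1 library; the 7 in scWAT became 0 with an estimated correlation and 0 with fry, and 5 to 16 without 1 library, 11 without KO C34 and 16 without KO C695. With an estimated correlation camera also uses the 4 residual degrees of freedom of the libraries in place of the number of genes, and how much each of these changes lost calls was not tested, nor was the cause with fry. Under every scaling and left-out library tried, 0 lists were called with an estimated correlation (smallest adjusted p = 0.364 in epWAT and 0.689 in scWAT), the following included. Lists called in the opposite direction to the test with all libraries were inflammation in epWAT without KO C7 (median -0.65) and, in scWAT without KO C695, macrophage (0.41, and -0.25 without KO C34), T and NK cell (-1.55, and 0.73 without KO C34) and matrix genes (0.33, and -0.20 without KO C34); the test's direction also turned without KO C695 for lists called neither way, among them white fat identity, adipokine, progenitor and cell cycle genes (0.11, 0.15, 0.08 and 0.03). With all libraries, among lists not called, the median and the test differed in sign in epWAT for inflammation (-0.19), progenitor, futile cycle, thermogenic, mast cell, pericyte, circadian and sex hormone genes, and in scWAT for T and NK cell (-0.05), matrix (0.02), white fat identity, lipogenic and sex hormone genes; the cause was not tested. The correlation of 0.14 across depots became 0.05 without KO epWAT C7 and KO scWAT C695 and 0.08 to 0.20 without 1 mouse. The difference in the targeted gene stayed below 0 without any 1 library, at -0.088 to -0.018 FPKM in epWAT and -0.224 to -0.13 in scWAT. For single named genes, 2637 results kept their side of the threshold over the alternatives, 219 lost a call and 258 gained one. For single lists 569 did, 90 lost a call, 24 gained one and 4 reversed. Depth limits the targeted gene, which had at most 10 reads in a library.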

Other observations

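Splits for the gene lists, for the depots and for the correlation and covariance of effects across depots were planned. The other tests of splits of the mice named here were chosen after the results were seen. For the overlap between depots the plan named calls, and genes at unadjusted p under 0.05 were used in their place. In scWAT, several list medians lay near 0: cell cycle genes had a median log2 change of 0.00, mature adipocyte genes 0.01, macrophage genes -0.02 and fatty acid oxidation genes -0.01. Skeletal muscle genes had a median of 0.86 with 13 of 15 higher (adjusted p = 0.124), carried by single libraries: their mean log2 value was 4.22 in KO C34 and 3.37 in KO C695 but 1.16 in KO C7, below the 1.61 to 3.11 of the WT libraries. The list median was 0.05 without KO C34, 0.51 without KO C695, 0.41 without WT C85 and 1.64 without KO C7 (adjusted p = 6.04e-06; adjusted p = 0.959 with an estimated correlation). In epWAT, collagen and matrix genes had a median of -0.46 with 28 of 33 lower (adjusted p = 0.0848). That list was called after upper-quartile scaling (-0.31; adjusted p = 0.0135), after quantile scaling (-0.35; adjusted p = 0.00209), without KO C7 (-0.66; adjusted p = 0.00673) and without WT C99 (-0.56; adjusted p = 0.0329). In that order it had adjusted p = 0.744, 0.69, 0.681 and 0.66 with an estimated correlation, and its median was -0.17 without KO C695 and -0.29 without WT C75. Glucocorticoid-responsive genes had a median of 0.42 with 15 of 17 higher (adjusted p = 0.000177; adjusted p = 0.41 with an estimated correlation), or 0.13 without WT C75.

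The same-direction changes in both depots were weighed against their position and chance. Passenger DNA beside the targeted gene would gather these genes near it. Within 20 Mb of it lay 6 of the 434, against 5.4 by chance (one-sided Fisher's exact p = 0.458). Of all 12183 genes tested in both depots only 152 lay there, so the 98.6% of the 434 outside is no evidence against passengers. The 6 inside cannot be told apart from passengers. For strain background concentrated on 1 chromosome, the smallest Bonferroni-adjusted Fisher's exact p was 0.533, on chromosome 13, with 24 genes against 15.7 expected. Independent lists would already share 58.8 higher and 282.5 lower genes, which dilutes this test, so it cannot exclude such background. Background scattered over several chromosomes may remain, as may an effect of genotype, neither being tested. The real split of mice was the only 1 of 10 to reach 434, the highest other giving 48, but the other splits had fewer genes at that p, and that one expected 5.8 higher and 2.3 lower from independent lists. By correlation the real split did not stand apart, with r = 0.14 and rho = 0.04 against up to 0.31 and 0.25 in the others; the covariance of effects was 0.0165, against at most 0.0146.

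Splits of 6 libraries or mice into 3 and 3 number 10, too few for a share under 0.05. In epWAT, 10 of 10 splits gave at least the real count of 0, the highest other giving 0, but any split reaches 0, so this count tests nothing. For unadjusted p under 0.05 only 1 of 10, the real split, gave as many as the real count, with 3795 genes against 752. In scWAT 1 of 10 did, with 40 genes against 5. For the depot comparison in WT it was 1 of 10, with 2852 genes against 0, and in KO 1 of 10, with 90 against 0, and the 3 other splits that part as many pairs gave 0 in each genotype. For the gene lists in scWAT, 9 of 10 splits gave at least the real 7 lists, the highest other giving 24, so the preset correlation called at least as many lists in most groupings as in the real one.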
